A study of Homo sapiens with 23 samples.

How the data were processed

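RNA from human blood leukocytes was measured on Affymetrix HG-U133 Plus arrays in 23 samples, 11 taken before extracorporeal photopheresis (ECP) and 12 after it. ECP exposes leukocytes outside the body to a psoralen and long-wave ultraviolet light. Per the labels, the earlier samples came from leukapheresis or, for 3 normal donors, from the treatment device, and the later samples were kept overnight in serum-supplemented medium in a platelet storage bag after ECP. The labels give 3 samples before and 3 after ECP from patients with cutaneous T cell lymphoma (CTCL), 3 and 3 from patients with graft versus host disease (GVHD), and 5 and 6 from normal donors. A stage directly after ECP and before incubation, named in the series' design text, was not analysed here.

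The deposited values were 1 linear signal intensity per probe set and array, already summarised by the authors. Total RNA was isolated on columns and amplified in 1 or 2 cycles, per the labels' protocols, which do not say which sample had which. The method of summarising and scaling was not given in the sources used here, and the values did not share their quantiles between arrays. The table held 54675 probe sets without missing values, of which 62 were controls. Array medians lay between 37.5 and 42.5, single values between 8.1 and 26996.8, and 0 pairs of arrays held identical values. Per the labels, 2 of the normal samples taken after ECP rested on data from 2 arrays each, and 1 sample titled as taken after ECP carried a leukapheresis entry; its title was followed. An array gives no count depth, so the number of arrays limits the precision.

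Probe sets were named through the platform's annotation table: 41097 had 1 gene symbol, 1801 had several and were left out, and 11777 had none. Of the named probe sets, 41043 were matched by gene number to the RefSeq gene table of assembly GRCh38.p14, which was used for names and for gene lengths, with no coordinates taken from it. XIST, its antisense gene and genes of the Y chromosome were removed before any step. Signals were quantile normalised between arrays with limma, 16 was added, and log2 was taken, so that fold changes of dim genes are understated. Each gene was represented by its probe set of highest mean over all samples. Of 19740 genes, the lowest 25% by mean were left out and 14805 were tested.

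One mean per group was fitted with lmFit and eBayes of limma over all 23 samples, which shared 1 estimate of the spread per gene, with 19.6 total degrees of freedom. The all-donor comparison was the equally weighted mean of the 3 post minus pre differences. Further comparisons were the difference within CTCL, GVHD and normal donors, the difference between the mean change of the patient groups and the change of normal donors, the same between CTCL and GVHD, and the levels before ECP between the donor groups. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and the threshold was an adjusted p of 0.05. The series' design text has the stages taken from the same donors, but the labels do not say that a replicate number marks 1 donor across stages, so no donor term was used; a fit with it was an alternative. The labels call the samples of a group biological replicates.

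Before the data were examined, 30 gene lists of 646 genes were fixed, of which 573 were tested: markers of monocytes, dendritic cell differentiation, dendritic cell maturation, macrophages, T cells, NK and cytotoxic cells, B cells, plasmacytoid dendritic cells, neutrophils, erythroid cells and platelets; MHC class I and class II antigen presentation, immune regulation, inflammatory cytokines and chemokines, NF-kappa-B targets, type I interferon response, p53 targets, NRF2 oxidative stress response, heat shock response, unfolded protein response, hypoxia and glycolysis, lipid handling, lysosome, integrins and adhesion, immediate early genes, cell cycle, ribosomal proteins, and genes raised and genes lowered in Sezary cells. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 30 lists; camera with an estimated correlation and fry were alternatives. The lists share some genes, and several monocyte, macrophage and dendritic cell markers are expressed by more than 1 of these cell types.

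Genes named in the text followed a rule also fixed beforehand. A named gene had to pass the threshold and have a mean in its higher group at or above the median of the genes tested (7.21). The rule took the 12 highest and 12 lowest changes over all donors with 1 sign in all 3 donor groups, the 4 highest and lowest within each donor group, the 6 highest and lowest for each difference between changes, the 5 highest and lowest for each comparison before ECP, up to 4 members of each list with up to 2 opposite ones, and 21 sentinel genes whatever their result. Where no gene passed, the 2 of smallest p were given. A few genes outside the rule are marked as chosen after their values were seen.

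The fit was tested on simulated data in which 200 of the 14805 genes changed by 1.41, 2, 4 or 8 times, 50 at each size. At 2-fold, 92% were recovered in the all-donor comparison, 46% within CTCL, 48% within GVHD, 82% within normal donors, 48% for the difference between patients and normal donors and 38% for that between CTCL and GVHD. False calls made up between 4.27% and 8.97% of calls, and 0 of the 30 lists was called in any comparison by limma's camera. The simulated genes were drawn independently of one another. The lists in these simulated data therefore say nothing of false calls among lists whose members vary together. The simulated data also held no effect shared by the genes of 1 library. The shares of false calls and of genes recovered may therefore not hold for the real samples.

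The alternatives set beforehand were median scaling, offsets of 1 and 64, no filter and a stricter filter on dim genes, the mean of all probe sets, a trended and robust variance, array weights, the replicate number as a fixed or random block, only the groups compared, each sample left out, the samples with 2 arrays or with the leukapheresis entry left out, normal donors from the treatment device alone, the alternative list tests and a 2-fold minimum. Median scaling was applied to the linear signals before the offset. After the data were seen, 2 sets of libraries were defined by technical measures. The 3' biased set held 2 normal donor libraries whose actin control had a 3'/5' signal ratio over 2-fold, and the low upper quartile set held 3 patient libraries whose deposited upper quartile was under 110. Fits without each set, without both, with each set as a block and with the actin ratio as a covariate were added. A comparison of patients with normal donors after ECP and the tests of gene length were also added after the data were seen. R 4.3.3, limma 3.58.1, statmod 1.5.0, python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.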

Results

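Blood leukocytes were profiled before ECP (n = 11) and after ECP with overnight incubation (n = 12). The series addresses whether ECP drives monocytes to become dendritic cells, the cells that present antigen to T cells. The samples came from patients with CTCL (3 before, 3 after), patients with GVHD (3 before, 3 after) and normal donors (5 before, 6 after). Levels are log2 of the normalised signal plus 16, given as mean ± SD over samples, and changes are log2 differences ± SE. The first principal component held 41% of the variance and put all 11 samples taken before ECP below all 12 taken after it.

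Over all donors, GPNMB, a glycoprotein of macrophages and dendritic cells, rose by 6.71 ± 0.29 after ECP, or at least 105-fold, since its signal was below the array median in all 11 samples before ECP. Its level in normal donors was 5.32 ± 0.06 before (n = 5) and 11.53 ± 0.71 after ECP (n = 6), in CTCL 5.28 ± 0.12 and 11.76 ± 1.16 (n = 3 each), and in GVHD 5.16 ± 0.09 and 12.59 ± 1.24 (n = 3 each). The chemokines CXCL5 and CCL2 rose by 5.56 ± 0.34 and 5.01 ± 0.92, and the matrix protein gene SPP1 rose by 4.32 ± 0.47. SLC7A11, the cystine transporter subunit, rose by 5.02 ± 0.26, and the scavenger receptor gene OLR1 rose by 4.32 ± 0.32. Further genes among the 12 highest were COXFA4L3 (5.77), FPR3 (5.41), VMO1 (5.20), SDC2 (4.69), SLC16A10 (4.57) and MMP19 (4.49).

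Among the 12 lowest, DPYD, which breaks down pyrimidines, fell by 4.71 ± 0.29, from 10.94 ± 0.47 to 7.44 ± 1.15 in normal donors and from 10.90 ± 0.23 to 5.49 ± 0.23 in CTCL. CX3CR1, the fractalkine receptor of patrolling monocytes and cytotoxic lymphocytes, fell by 4.27 ± 0.47. The monocyte gene MS4A6A fell by 3.97 ± 0.42 and the coagulation factor gene F13A1 fell by 3.56 ± 0.42. The granzyme gene GZMA, the platelet tubulin gene TUBB1 and the B cell genes BANK1 and TCL1A fell by 3.70, 3.67, 3.63 and 3.41. UTRN, PRKCB and DIAPH2 fell by 3.63, 3.56 and 3.47, and MPP7 fell by 3.39.

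In the limma fit, 6458 of 14805 genes changed (43.6%), 3248 up and 3210 down, and 1726 of them by at least 2-fold, 780 up and 946 down. Without 2 normal donor libraries with 3' biased signal, 7102 genes changed, 6363 of them shared in direction with the 6458. Without 3 patient libraries of low upper quartile, 4739 changed, 4526 of them shared.

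**Figure D1:**
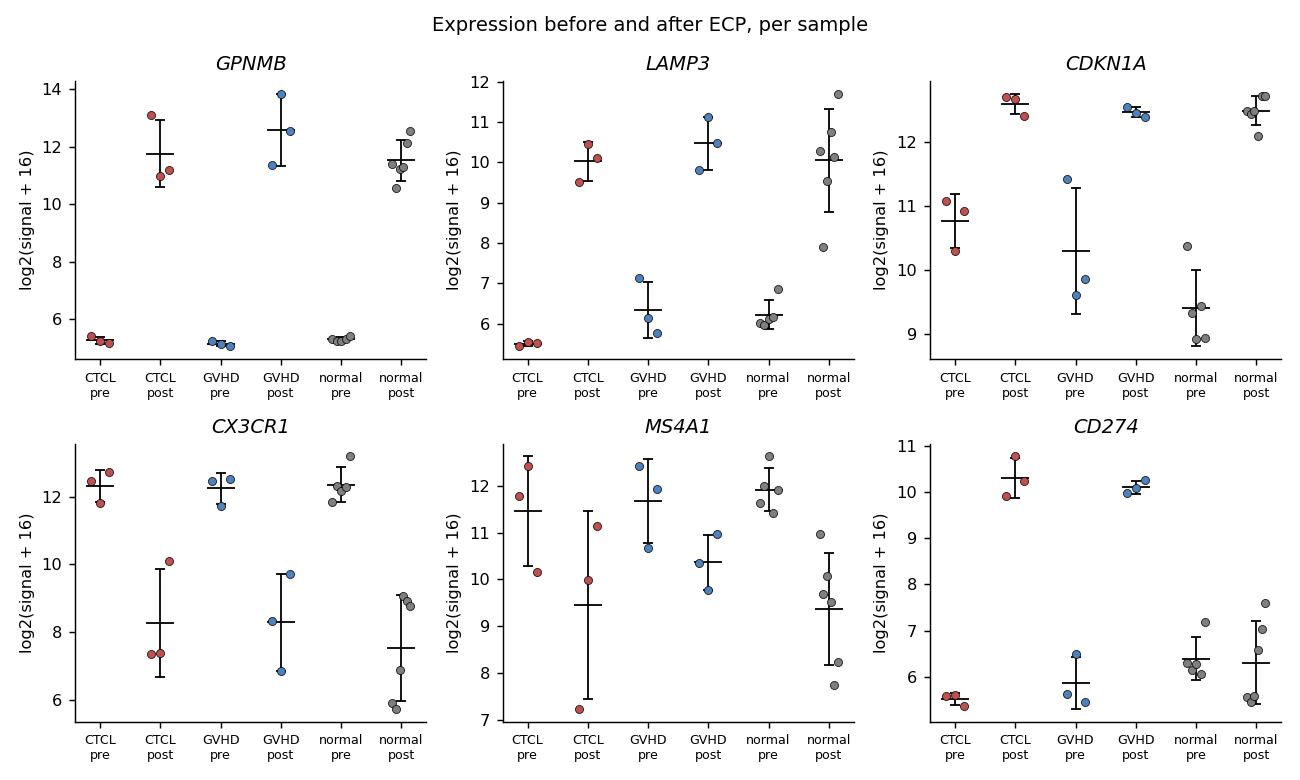
Normalised log2 signal of 6 genes in each sample (points) of the 6 groups, with the group mean and SD (bars); before is "pre" and after is "post". GPNMB lay between 5.08 and 5.42 in all samples before ECP and between 10.56 and 13.85 after it, and CD274 after ECP lay between 9.97 and 10.25 in GVHD but between 5.47 and 7.59 in normal donors.

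Dendritic cell maturation markers rose over all donors. Of 23 measured, 16 rose, 1 fell and 6 did not pass (17 and 1 adjusted over the list alone; camera adjusted p = 1.54e-07, adjusted p = 0.0353 with an estimated correlation). The call with an estimated correlation was lost without the libraries of low upper quartile (adjusted p = 0.0837), without the 3' biased libraries (0.0863) and within normal donors (0.156). The list median was 1.09 with all libraries, 1.13 and 1.07 without each set and 1.01 in normal donors, and camera at the preset correlation passed in each. In the same comparison the B cell, NK, T cell and platelet marker lists had medians of -1.86, -2.00, -1.18 and -1.07, beside this and every other list given for all donors. LAMP3, a membrane protein of mature dendritic cells, rose by 4.16 ± 0.33, the chemokine gene CCL22 by 3.01 ± 0.25, the inhibitory ligand gene CD274 by 2.98 ± 0.24 and the signalling adaptor gene TRAF1 by 2.09 ± 0.18, whereas the cytokine gene IL15 fell by 0.80 ± 0.23. The co-stimulatory ligand genes CD80 and CD86 rose by 1.15 ± 0.10 and 1.09 ± 0.30, and FSCN1, which bundles actin, rose by 1.60 ± 0.18. CD83 (0.03 ± 0.38), CD40 (0.37 ± 0.15, adjusted p = 0.0552) and CCR7 (0.55 ± 0.33) did not pass. In normal donors CD274 (-0.09 ± 0.34), TRAF1 (0.32 ± 0.25) and CD80 (0.23 ± 0.14) did not pass, and their change differed from that in patients (4.60, 2.66 and 1.39), where CD274 rose by 4.78 in CTCL and 4.24 in GVHD. CD86 passed in normal donors (2.17 ± 0.43), with 0.12 ± 0.57 in CTCL and 0.97 ± 0.57 in GVHD, and the difference did not pass (adjusted p = 0.09).

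Dendritic cell differentiation markers split. Of 23 measured, 5 rose and 9 fell (6 and 9 adjusted over the list alone; camera adjusted p = 0.207). OLR1 and the metalloprotease gene ADAMDEC1 rose by 4.32 and 3.44, CD209 rose by 0.66 ± 0.24, and CD1C and FCER1A, markers of circulating conventional dendritic cells, fell by 2.80 ± 0.14 and 2.78 ± 0.40. ITGB5 (0.08 ± 0.22) did not pass. Plasmacytoid dendritic cell markers fell, 7 of 10 with 1 risen (7 and 1 adjusted over the list alone; camera adjusted p = 0.00604, adjusted p = 0.321 with an estimated correlation). TCF4 and PLD4 fell by 1.61 and 1.38, and IL3RA rose by 0.76.

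Over all donors, monocyte markers fell, 12 of 21 with 2 risen (12 and 2 adjusted over the list alone; camera adjusted p = 0.000313, adjusted p = 0.188 with an estimated correlation). FCN1, CCR2 and CLEC12A fell by 3.17, 2.50 and 2.45, TLR2 rose by 0.91, and CD14, the lipopolysaccharide co-receptor, did not pass (-0.04 ± 0.17). Within CTCL and GVHD 8 and 13 fell and 0 rose (11 and 15 fallen adjusted over the list alone; medians -1.15 and -1.69). In normal donors 3 rose and 5 fell, and the list did not pass (5 and 5 adjusted over the list alone; median 0.14, mean -0.375, camera adjusted p = 0.88). Without the libraries of low upper quartile 6 fell in GVHD (11 adjusted over the list alone, median -1.45). In CTCL, where 1 sample before ECP was then left, the list median was -1.54. Macrophage markers rose, 10 of 22 with 3 fallen (10 and 4 adjusted over the list alone; camera adjusted p = 0.0204, adjusted p = 0.423 with an estimated correlation). The proteases MMP9 and CTSL rose by 3.34 and 3.01, and the complement gene C1QA and the folate receptor gene FOLR2 fell by 1.74 and 1.13.

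Antigen presentation genes showed no common shift. For MHC class II, 3 of 18 rose and 7 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.29): the proteases LGMN and CTSB rose by 3.66 and 1.56, HLA-DOB and HLA-DMB fell by 1.92 and 1.57, and HLA-DRA (-0.09 ± 0.14) did not pass. For MHC class I, 3 of 17 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.897), with the peptide transporter gene TAP1 risen by 1.21 and NLRC5 fallen by 0.71 (-0.09 in CTCL, -0.35 in GVHD and -1.70 in normal donors). Immune regulation genes rose, 11 of 20 with 2 fallen (12 and 2 adjusted over the list alone; camera adjusted p = 0.00189, adjusted p = 0.188 with an estimated correlation). IDO1, which breaks down tryptophan, rose by 3.97 ± 0.31, the cytokine gene IL10 by 2.39 ± 0.31 and THBS1 by 3.17 ± 0.43, and the ectonucleotidase gene ENTPD1 fell by 1.83.

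Inflammatory cytokine and chemokine genes rose, 18 of 23 with 5 not passing (18 adjusted over the list alone; camera adjusted p = 1.19e-07, adjusted p = 0.151 with an estimated correlation). CXCL3, CXCL1 and TNF rose by 4.25, 4.16 and 1.91 ± 0.41. NF-kappa-B targets rose, 14 of 18 with 4 not passing (14 adjusted over the list alone; camera adjusted p = 6.72e-06, adjusted p = 0.164 with an estimated correlation), among them IRAK2 and NFKBIE by 2.12 and 1.70. Over all donors, type I interferon response genes rose, 7 of 25 with 18 not passing (6 adjusted over the list alone; camera adjusted p = 0.0189, adjusted p = 0.683 with an estimated correlation), among them RSAD2 and HERC5 by 2.16 ± 0.81 and 1.86 ± 0.50. In CTCL 4 rose and in GVHD 1 (4 and 0 adjusted over the list alone; medians 1.94 and 0.77). In normal donors 0 rose and 1 fell (0 adjusted over the list alone; median -0.35, camera adjusted p = 0.428). Without the libraries of low upper quartile 4 rose over all donors and 0 in CTCL or GVHD singly, and the list no longer passed in GVHD (median 0.76, camera adjusted p = 0.18). In CTCL, where 1 sample before ECP was then left, the list median was 2.62.

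The p53 targets, genes switched on by DNA damage, moved most uniformly of the rising lists. Of 25 measured, 22 rose and 3 did not pass (22 adjusted over the list alone; camera adjusted p = 1.2e-14, adjusted p = 0.00301 with an estimated correlation). The repair gene DDB2 rose by 2.88 ± 0.15, GADD45A by 2.75 ± 0.15, the p53 ligase gene MDM2 by 2.60 ± 0.16, and the cell cycle inhibitor gene CDKN1A by 2.37 ± 0.20, from 9.40 ± 0.60 to 12.50 ± 0.23 in normal donors. Over all donors, cell cycle genes fell, 13 of 27 with 2 risen (13 and 2 adjusted over the list alone; camera adjusted p = 0.0144, adjusted p = 0.644 with an estimated correlation). RRM2 and TOP2A fell by 2.47 and 0.81, and PCNA, a replication clamp that is also a p53 target, rose by 1.94 ± 0.17. In CTCL 3 fell and 1 rose and in GVHD 8 fell and 1 rose (10 in GVHD adjusted over the list alone; medians -0.40 and -0.59). The list did not pass in normal donors, where 1 fell and 2 rose (median -0.09, camera adjusted p = 0.773). Without the libraries of low upper quartile 20 fell over all donors and 12 in GVHD (20 and 18 adjusted over the list alone, medians -0.65 and -0.87). In CTCL, where 1 sample before ECP was then left, the list median was -1.03.

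Other stress lists rose in part. NRF2 response genes rose, 11 of 18 with 2 fallen (12 and 2 adjusted over the list alone; camera adjusted p = 3.66e-05, adjusted p = 0.188 with an estimated correlation), with SQSTM1 and TXNRD1 risen by 2.04 and 1.82. Heat shock genes rose, 8 of 14 with 1 fallen (8 and 1 adjusted over the list alone; camera adjusted p = 0.00647, adjusted p = 0.329 with an estimated correlation), with BAG3 and DNAJB4 risen by 1.67 and 1.59. Hypoxia and glycolysis genes rose, 17 of 25 with 2 fallen (17 and 2 adjusted over the list alone; camera adjusted p = 0.000198, adjusted p = 0.188 with an estimated correlation), with ADM and VEGFA risen by 1.65 and 1.57 (for VEGFA 0.27 in CTCL, 1.27 in GVHD and 3.18 in normal donors). In the unfolded protein response list 4 of 17 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.602), with ATF3 risen by 1.90 and PDIA4 fallen by 0.54.

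Lipid handling genes rose, 13 of 22 with 2 fallen (13 and 2 adjusted over the list alone; camera adjusted p = 0.000543, adjusted p = 0.249 with an estimated correlation). The cholesterol transporter genes ABCA1 and NPC1 and the lipid droplet gene PLIN2 rose by 2.56, 2.15 and 2.41, and the scavenger receptor gene CD36 fell by 2.04 ± 0.45. Lysosome genes rose, 16 of 22 with 2 fallen (17 and 2 adjusted over the list alone; camera adjusted p = 2.42e-06, adjusted p = 0.236 with an estimated correlation). GLA and NEU1 rose by 1.96 and 1.88 and CTSC fell by 1.19, and LAMP2 rose by 1.75 ± 0.21, but reversed to -0.12 under median scaling and -0.21 with an offset of 1, where another of its probe sets was the brightest.

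Integrin and adhesion genes went both ways, 7 of 23 up and 11 down (7 and 12 adjusted over the list alone; camera adjusted p = 0.1), with ITGB8 risen by 3.34 and ITGA4 and ITGAM fallen by 2.77 and 2.25. With the libraries of low upper quartile left out 4 rose and 11 fell, and the list passed downward (camera adjusted p = 0.0454, adjusted p = 0.289 with an estimated correlation). Immediate early genes also went both ways, 3 of 22 up and 8 down (4 and 9 adjusted over the list alone; camera adjusted p = 0.275), with IER3 risen by 2.62 and KLF2 and MYC fallen by 2.18 and 1.89. Within groups this list passed camera downward in CTCL and GVHD (medians -0.72 and -0.77; adjusted p = 0.0259 and 0.019, adjusted p = 0.546 and 0.541 with an estimated correlation). It passed upward in normal donors (median 0.40; adjusted p = 0.0262, adjusted p = 0.553 with an estimated correlation), though not without the 3' biased libraries (adjusted p = 0.212). Over all donors 5 fell without the libraries of low upper quartile. Ribosomal protein genes fell slightly, 9 of 29 with 20 not passing (5 adjusted over the list alone; camera adjusted p = 0.00734, adjusted p = 0.627 with an estimated correlation), among them RPL14 and RPL3 by 0.49 and 0.47. The list median was -0.306 with all libraries, -0.256 without the 3' biased ones and -0.31 without those of low upper quartile, whereas the counts moved more. Without the 3' biased libraries 19 fell and 1 rose (20 and 1 adjusted over the list alone), and without those of low upper quartile 3 fell (0 adjusted over the list alone).

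Markers of 4 other kinds of blood cell fell over all donors. NK and cytotoxic markers fell, 18 of 21 (21 adjusted over the list alone; camera adjusted p = 1.19e-07, adjusted p = 0.277 with an estimated correlation), with KLRF1 and CTSW fallen by 3.21 and 3.15. B cell markers fell, 17 of 19 (19 adjusted over the list alone; camera adjusted p = 4.11e-10, adjusted p = 0.188 with an estimated correlation), with CD79B and MS4A1 fallen by 2.72 ± 0.27 and 1.96 ± 0.45. T cell markers fell, 16 of 25 (18, with 1 risen, adjusted over the list alone; camera adjusted p = 0.000151, adjusted p = 0.423 with an estimated correlation), with THEMIS and CD3D fallen by 2.42 ± 0.44 and 1.18 ± 0.45. In normal donors 21 T cell markers fell, in CTCL 3, and in GVHD 1 fell and 1 rose (25, 2 and 1 fallen adjusted over the list alone), with medians of -2.22, -0.90 and -0.61. In GVHD the list did not pass (camera adjusted p = 0.194), but did without the libraries of low upper quartile (adjusted p = 0.0479, adjusted p = 0.654 with an estimated correlation). Platelet markers fell, 13 of 16 (13 adjusted over the list alone; camera adjusted p = 0.000233, adjusted p = 0.385 with an estimated correlation), with NRGN and SPARC fallen by 2.23 and 2.02. Of 20 neutrophil markers 4 fell (3 adjusted over the list alone; camera adjusted p = 0.26), with PADI4 fallen by 1.62. Neutrophil markers passed camera downward in GVHD, with 5 fallen (6 adjusted over the list alone; median -0.86; adjusted p = 0.0021, adjusted p = 0.367 with an estimated correlation). They passed upward in normal donors, with 1 risen and 1 fallen (1 and 1 adjusted over the list alone; median 0.80; adjusted p = 0.0266, adjusted p = 0.524 with an estimated correlation), though not without the 3' biased libraries (adjusted p = 0.0574). In CTCL the median was -0.31 (camera adjusted p = 0.151). It was -0.77 without the libraries of low upper quartile, which leaves 1 CTCL sample before ECP. All 10 erythroid markers missed the threshold (camera adjusted p = 0.539), HEMGN showing the largest change (-0.53 ± 0.24).

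Of 12 genes known to be raised in Sezary cells, the malignant T cells of leukaemic CTCL, 3 rose and 5 fell over all donors (3 and 6 adjusted over the list alone; camera adjusted p = 0.112), with TOX (-2.57) fallen and PLS3 risen (0.91; -0.19 in normal donors). With the libraries of low upper quartile left out 0 rose and 4 fell, and this list passed downward (camera adjusted p = 0.0469, adjusted p = 0.268 with an estimated correlation); 0 of the MHC class I genes and 2 neutrophil markers then fell. Of 11 genes known to be lowered in them, 1 rose and 6 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.0276, adjusted p = 0.398 with an estimated correlation). The members that fell include the cytotoxic genes PRF1 and GNLY, by 2.28 and 2.21, and LMNA, of the nuclear lamina, rose by 3.11. In all, 21 of 30 lists passed camera, 12 up and 9 down, and 2 lists, p53 targets and dendritic cell maturation, passed with an estimated correlation. With either set of libraries that stood apart left out, only 1, p53 targets, did (adjusted p = 0.00934 without those of low upper quartile and 0.00421 without the 3' biased ones). Besides the lists already described within donor groups, macrophage markers missed the camera threshold in CTCL (adjusted p = 0.196), heat shock genes in normal donors (0.264), hypoxia and ribosomal protein genes in GVHD (0.109 and 0.0601) and the genes lowered in Sezary cells in CTCL and GVHD (0.157 and 0.194). Ribosomal protein genes did pass in GVHD without the 3' biased libraries (camera adjusted p = 0.00696, adjusted p = 0.622 with an estimated correlation). All 30 lists kept their direction and call under median scaling.

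**Figure D2:**
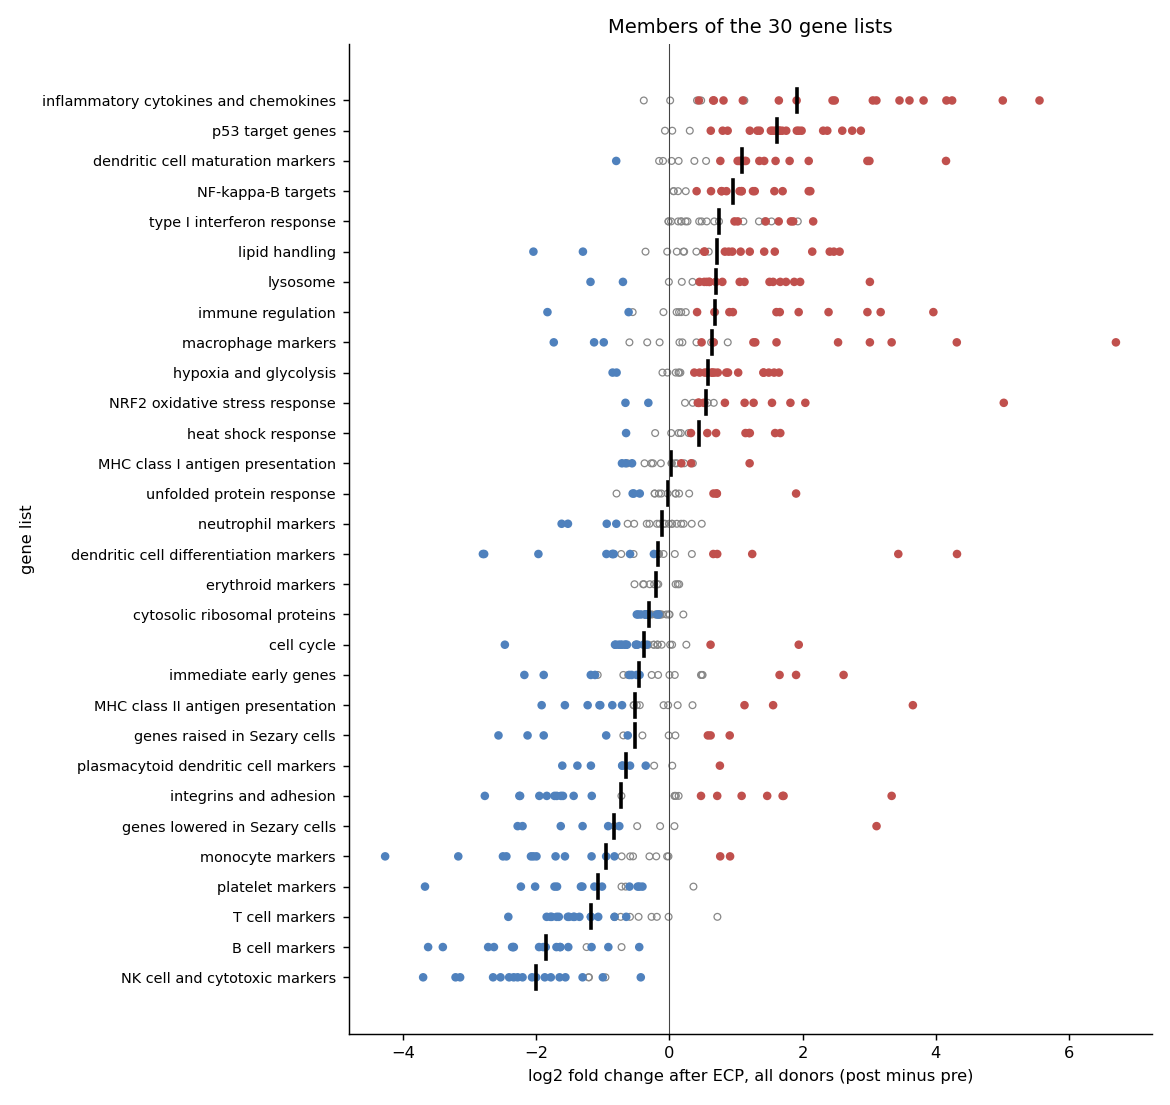
Change after ECP over all donors (x axis, log2) of each measured member of the 30 gene lists (y axis); filled points passed an adjusted p of 0.05, open points did not, and black bars mark list medians. The p53 targets had a median of 1.61, inflammatory cytokines and chemokines 1.91, B cell markers -1.86 and NK and cytotoxic markers -2.00.

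Within CTCL, GPNMB, CXCL5, CCL2 and the metalloprotease gene MMP19 rose by 6.48 ± 0.54, 5.60 ± 0.64, 5.48 ± 1.74 and 5.37 ± 0.52 (n = 3 before, 3 after). DPYD (-5.42 ± 0.55), MS4A6A (-4.80 ± 0.79), the carboxypeptidase gene CPVL (-4.35 ± 0.77) and F13A1 (-4.09 ± 0.79) fell. In the limma fit 3224 genes changed, 1813 up and 1411 down (56.2% up; 70.6% up under median scaling). Without the 2 libraries of low upper quartile in this group and the 1 in GVHD, 889 genes changed, 837 of them shared. Without CTCL sample 2 before ECP alone, 2057 changed.

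Within GVHD, GPNMB rose by 7.43 ± 0.54, COXFA4L3 by 6.06 ± 0.72, CXCL5 by 5.89 ± 0.64 and SLC7A11 by 5.44 ± 0.49 (n = 3 before, 3 after). DPYD (-5.20 ± 0.55), the kinase gene PRKCB (-4.43 ± 0.47), MS4A6A (-4.29 ± 0.79) and TUBB1 (-4.13 ± 1.13) fell. With limma, 2906 genes changed, 1577 up and 1329 down (54.3% up; 68.2% up under median scaling).

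Within normal donors, COXFA4L3 rose by 6.49 ± 0.54, GPNMB by 6.21 ± 0.40, the ribonuclease gene RNASE1 by 6.20 ± 0.77 and OLR1 by 6.14 ± 0.45 (n = 5 before, 6 after). CX3CR1 (-4.82 ± 0.66), the cytotoxic cell genes GZMA (-4.12 ± 0.73) and PRF1 (-3.51 ± 0.66) and the delta T cell receptor segment TRDV3 (-3.62 ± 0.70) fell. A total of 4081 genes changed with limma, 1748 up and 2333 down.

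The donor groups, which share no samples, had genes in common. They do share 1 estimate of the spread per gene, so their calls are not independent. The counts given for independent lists are therefore only a rough reference. CTCL and GVHD shared 1277 risen genes where independent lists would share 193, and 998 fallen genes where 127 would be shared. CTCL and normal donors shared 779 risen and 866 fallen genes (214 and 222 for independent lists), and GVHD and normal donors 723 and 838 (186 and 209). Across genes, which are not independent replicates, Pearson's r of the changes was 0.937 between CTCL and GVHD, 0.656 between CTCL and normal donors and 0.651 between GVHD and normal donors. Among genes called in all 3 groups, 627 rose and 710 fell in each.

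Whether patients' cells responded otherwise than those of normal donors was tested as a difference between changes. CD274, which encodes PD-L1, went from 5.52 ± 0.13 to 10.30 ± 0.43 in CTCL and from 5.86 ± 0.56 to 10.10 ± 0.14 in GVHD (n = 3 each), but from 6.40 ± 0.46 (n = 5) to 6.31 ± 0.90 (n = 6) in normal donors, a difference of 4.60 ± 0.47. SPINK1, SLAMF7 and ACOD1, which makes itaconate, also had a higher change in patients, by 4.18 ± 0.46, 3.45 ± 0.47 and 3.37 ± 0.32, as did IL6 and TFPI2, by 3.61 ± 1.00 and 3.37 ± 1.00. THBD, the thrombin receptor thrombomodulin, went from 7.17 ± 0.79 to 11.11 ± 1.02 in normal donors but from 10.93 ± 0.27 to 9.22 ± 0.91 in CTCL and from 9.61 ± 1.40 to 8.21 ± 0.92 in GVHD, a difference of -5.50 ± 0.74. Lower changes in patients were also seen for FCAR (-4.0), PHLDA1 (-3.89), IL1R2 (-3.86), GPR160 (-3.63) and EREG (-3.62). Some of these differences lay in the levels before ECP. PHLDA1 and FCAR were then already higher than in normal donors, by 4.45 and 3.64 in CTCL and by 3.64 and 2.98 in GVHD. For GPR160 the gap of patients to normal donors was 0.18 before ECP and -3.45 after it.

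Of the lists, 10 passed camera for this difference. Before ECP, T cell markers were already lower in both patient groups by camera at the preset correlation. Monocyte, immediate early and cell cycle lists were already higher there. The change was higher in patients for type I interferon response genes (3 of 25 passed singly; 5 adjusted over the list alone; camera adjusted p = 4.27e-05, adjusted p = 0.72 with an estimated correlation), T cell markers (6 of 25; 8 adjusted over the list alone), dendritic cell maturation markers (4 of 23; 7, with 1 lower, adjusted over the list alone), heat shock genes (3 of 14 adjusted over the list alone, and none over all genes) and MHC class I genes (1 of 17, and none adjusted over the list alone). It was lower in patients for monocyte markers (4 of 21; 10 adjusted over the list alone; camera adjusted p = 8.28e-07, adjusted p = 0.264 with an estimated correlation), immediate early genes (9 of 22; 11 adjusted over the list alone), neutrophil markers (3 of 20; 9 adjusted over the list alone), hypoxia and glycolysis genes (5 of 25; 9 adjusted over the list alone) and cell cycle genes (2 of 27; 2 adjusted over the list alone). With an estimated correlation these had adjusted p of 0.72 for T cell, heat shock and MHC class I genes, 0.633 for maturation markers, 0.406 for immediate early, neutrophil and hypoxia genes and 0.822 for cell cycle genes. Without the libraries of low upper quartile all 10 lists passed, with other counts of members: 0 for interferon, 2 for T cell, 2 for monocyte, 1 for immediate early, 2 for hypoxia and 7 for cell cycle genes (2, 2, 2, 11, 5 and 18 adjusted over the list alone). Maturation markers then had 3, neutrophil markers 2 and heat shock and MHC class I genes 0 (4, 4, 0 and 0 adjusted over the list alone).

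By limma, the change differed for 1421 genes, 943 higher and 478 lower in patients (66.4% higher; 83% under median scaling, which moved the median of all genes to 0.119). Of the 1421, 737 already differed between patients and normal donors before ECP, 657 differed after it and 103 in both. Without the 3 libraries of low upper quartile 389 genes passed, 354 of them shared, with CD274 at 4.47 ± 0.57 and THBD at -5.39 ± 0.91, both passing. IL6, TFPI2 and PHLDA1 stood at 3.44 ± 1.18, 3.44 ± 1.25 and -3.46 ± 1.01, against 3.61 ± 1.00, 3.37 ± 1.00 and -3.89 ± 0.85 with all libraries, and with fewer samples and wider errors no longer passed (adjusted p = 0.13, 0.157 and 0.0779). With normal donors before ECP limited to the treatment device, 849 genes passed.

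**Figure D3:**
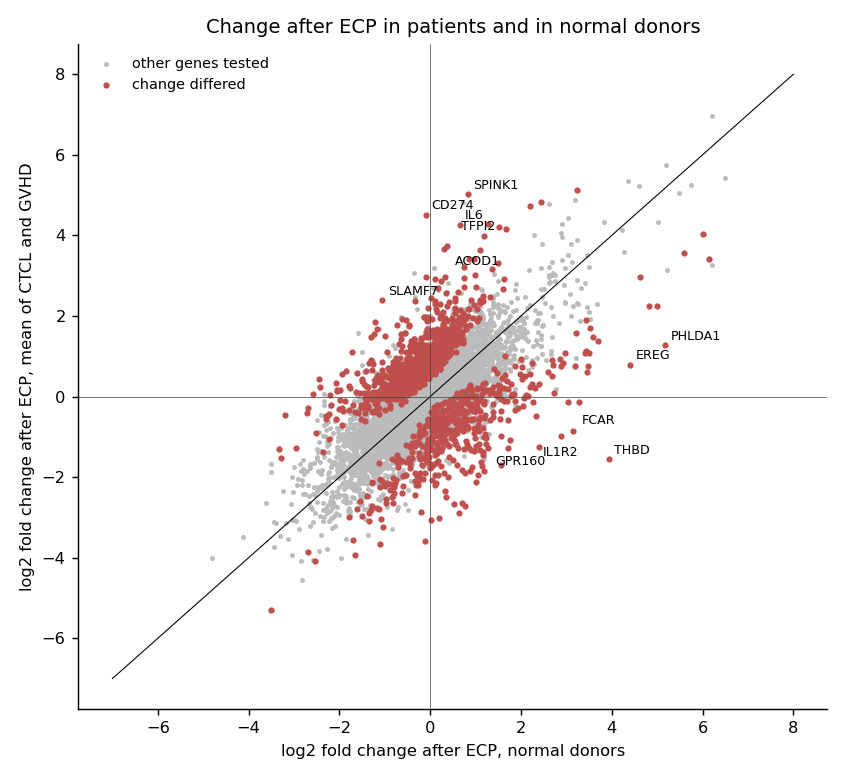
Change after ECP (log2) of each gene tested in normal donors (x axis) and in patients as the mean of CTCL and GVHD (y axis); red points are the 1421 genes whose change differed, and the diagonal marks equal change. CD274 lay above the diagonal with a difference of 4.60 and THBD below it with a difference of -5.50.

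Between CTCL and GVHD, the named genes closest to a differing change were the autophagy gene MAP1LC3A (0.62 ± 0.17) and ANKRD22 (1.96 ± 0.58), both with an adjusted p of 1. limma called 0 genes, and 116 had an unadjusted p under 0.05 where 740 would be expected by chance. At the preset correlation 8 lists passed camera, among them type I interferon response genes with a higher change in CTCL (adjusted p = 0.000473), and 0 passed with an estimated correlation (adjusted p of 0.703 or more). In simulated data of this comparison 38% of 2-fold and 84% of 8-fold differences were recovered. The simulated genes varied independently, whereas libraries of low upper quartile lie in both patient groups before ECP. This recovery may therefore not hold for the real samples.

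Before ECP, PHLDA1 was 10.71 ± 0.93 in CTCL (n = 3) and 6.26 ± 0.36 in normal donors (n = 5), a gap of 4.45 ± 0.74. EMP1, THBD, the chemokine gene CXCL2 and the IgA receptor gene FCAR were higher by 4.0, 3.76, 3.65 and 3.64. Among the lowest genes, the T cell genes MAL, CD28 and TRAT1 were lower (-4.01, -3.28 and -3.19), as were LRRN3 (-3.27) and INPP4B (-3.11). Of 25 T cell markers, 10 were lower (13 adjusted over the list alone; camera adjusted p = 4.21e-08, adjusted p = 0.534 with an estimated correlation). Of 10 erythroid markers, 4 were higher (7 adjusted over the list alone; camera adjusted p = 0.000233, adjusted p = 0.534 with an estimated correlation). Of 22 immediate early genes, 3 were higher (6 adjusted over the list alone; camera adjusted p = 0.000287, adjusted p = 0.534 with an estimated correlation). Of 23 inflammatory cytokine and chemokine genes, 3 were higher and 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.00264, adjusted p = 0.534 with an estimated correlation). Cell cycle, monocyte, macrophage, lysosome and unfolded protein response lists also passed upward (camera adjusted p = 0.00264, 0.0048, 0.00495, 0.018 and 0.0328, each with an adjusted p of 0.534 or more with an estimated correlation). In the limma fit 1928 genes differed, 745 higher and 1183 lower in CTCL (38.6% higher; 18.2% under median scaling, which moved the median of all genes to -0.145). Of the 3 CTCL libraries 2 had a low upper quartile, and without these libraries, which leaves 1 CTCL sample assumed to vary like the other groups, 4 genes passed, 0 shared with the 1928 in limma (1080 at an unadjusted p under 0.05). There the 5 higher genes named here stood between 3.29 and 4.07, PHLDA1 at 3.41 ± 1.16, and the 5 lower ones between -3.10 and -2.45, MAL at -3.10 ± 0.83, without passing. The T cell, erythroid, immediate early and inflammatory lists then kept their directions, with medians of -1.75, 1.05, 0.61 and 0.47, and cell cycle genes had a median of 1.19.

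In GVHD before ECP, the delta globin gene HBD was 10.28 ± 1.10 (n = 3) and 6.62 ± 1.17 in normal donors (n = 5), a gap of 3.66 ± 0.57. PHLDA1, CXCL2, FCAR and the fatty acid receptor gene FFAR2 were higher by 3.64, 3.22, 2.98 and 2.95. LRRN3, MAL, AQP3, ADTRP and TMEM204 were lower (-3.31, -3.17, -2.87, -2.61 and -2.54). Of 10 erythroid markers, 7 were higher (9 adjusted over the list alone; camera adjusted p = 5.8e-11, adjusted p = 0.383 with an estimated correlation). Of 25 T cell markers, 7 were lower (8 adjusted over the list alone; camera adjusted p = 6.9e-06, adjusted p = 0.515 with an estimated correlation). Of 27 cell cycle genes, 2 were higher (7 adjusted over the list alone; camera adjusted p = 1.64e-06, adjusted p = 0.515 with an estimated correlation). Type I interferon response genes and neutrophil markers passed upward as lists with 0 members passing singly (medians 1.42 and 0.81; camera adjusted p = 0.000131 and 0.000194, adjusted p = 0.515 with an estimated correlation). Immediate early genes and monocyte markers passed upward with 3 of 22 and 2 of 21 (3 and 2 adjusted over the list alone; camera adjusted p = 0.000325 and 0.00136, adjusted p = 0.515 with an estimated correlation). Of 7 further lists up and 1 down, ribosomal protein genes, the smallest camera adjusted p was 0.00196, and each had an adjusted p of 0.515 or more with an estimated correlation. With limma, 748 genes differed, 169 higher and 579 lower in GVHD (22.6% higher; 10.1% under median scaling). Without the libraries of low upper quartile 291 genes differed, 243 of them shared, with HBD, PHLDA1, CXCL2, LRRN3, MAL and ADTRP passing. There 2 T cell markers were lower and 9 cell cycle genes higher (4 and 19 adjusted over the list alone). In the fit without the libraries of low upper quartile FCAR, FFAR2, AQP3 and TMEM204 stood at 2.97, 3.26, -2.95 and -2.22 without passing. With all libraries these were 2.98, 2.95, -2.87 and -2.54. Without GVHD sample 4 before ECP, 147 genes differed.

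Between CTCL and GVHD before ECP, the genes of smallest p were the potassium channel gene KCNMA1 (0.73 ± 0.19) and OSBP2 (-0.56 ± 0.15), both with an adjusted p of 1. limma called 0 genes, and 175 had an unadjusted p under 0.05 where 740 would be expected by chance. At the preset correlation 7 lists passed camera, all lower in CTCL, led by erythroid and T cell markers (adjusted p = 2.31e-07 and 5.6e-05), and 0 passed with an estimated correlation (adjusted p of 0.967 for each of the 7). In simulated data of this comparison 68% of 2-fold differences were recovered, without the libraries of low upper quartile that lie in both real groups. That share may therefore not hold for the real samples.

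**Figure D4:**
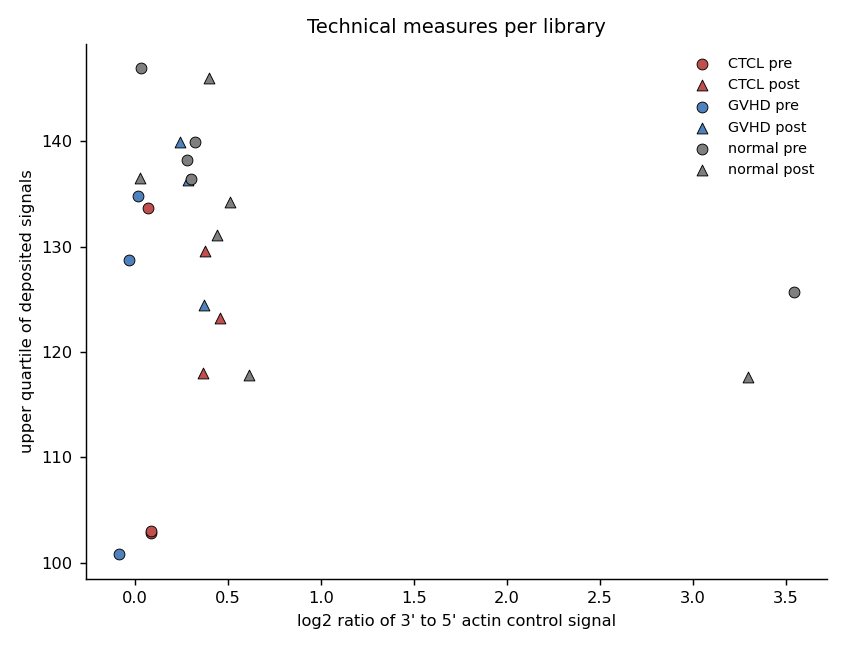
The log2 ratio of 3' to 5' actin control signal (x axis) and the upper quartile of the deposited signals (y axis) of each library, with circles for before and triangles for after ECP. The actin ratio was 3.54 and 3.30 in 2 normal donor libraries and at most 0.615 in the other 21, and 3 patient libraries from before ECP had an upper quartile between 100.8 and 103 where the others had at least 117.6.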

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

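Tests chosen after their result was seen were those on the 3 libraries of low upper quartile, on the 3' bias and on the harvest as causes of the differences before ECP; the other tests of this part were set before.

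The change after ECP differed between patients and normal donors for 1421 genes by the fitted difference of changes. Higher changes in patients were those of CD274 (4.6), SPINK1 (4.18), IL6 (3.61), SLAMF7 (3.45), ACOD1 (3.37) and TFPI2 (3.37), and lower ones those of THBD (-5.5), FCAR (-4), PHLDA1 (-3.89), IL1R2 (-3.86), GPR160 (-3.63) and EREG (-3.61). Lists past camera for this difference were monocyte markers (adjusted p = 8.28e-07), immediate early genes (8.28e-07), neutrophil markers (6.99e-06), T cell markers (2.26e-05), type I interferon response (4.27e-05), hypoxia and glycolysis (0.000357), cell cycle (0.00662), MHC class I (0.0117), heat shock (0.0147) and dendritic cell maturation (0.0229), each with 0.264 or more with an estimated correlation. Only 1 of 100 splits, the real one, gave as many genes, and the highest other gave 565. The 3 libraries of low upper quartile all lie in the real patient groups before ECP. These splits therefore cannot tell a difference in response from the placement of those libraries. Without those libraries 389 genes passed, 354 of them shared.

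Before ECP, 1928 genes differed between CTCL and normal donors and 748 between GVHD and normal donors, and 3 of the 6 patient libraries had a low upper quartile. These 3 gave 4758 genes against the 5 normal libraries and the 3 other patient libraries 649, and of the median gap of the first 1000 genes the others showed 29.6% against separate normal libraries (median of 10 splits of the normal donors). Those genes were ranked in the 3 low libraries, which by itself makes their gap smaller elsewhere. Of the 649 genes, 537 were shared in direction with the 4758, against the same normal libraries. Against separate normal libraries the 2 gaps had a Pearson's r across genes of 0.485 to 0.677. The 3' bias of 1 normal library was argued against as the cause, since 2155 genes differed for CTCL without the biased libraries. A smaller difference in 3' signal was not tested on its own. Before ECP the actin log2 ratio was -0.0839 to 0.0864 in the 6 patient libraries and 0.03439 to 0.3217 in the other normal ones. The harvest of normal donors' cells by 2 methods stays open: the 1000 genes ranked first between 3 patient libraries and 2 device libraries showed 63.8% of their median gap between the 3 other patient libraries and the 2 leukapheresis libraries. The range was 31% to 90.7% over 10 splits of the patient libraries, where 5 other splits of these 4 normal libraries gave 57% to 86%. Between all 3 device libraries, the 3' biased one included, and the 2 leukapheresis libraries limma called 0 genes (302 at an unadjusted p under 0.05). With so few libraries, that absence of calls cannot decide the question. Whether the low quartile reflects the array step or the cells in those 3 samples stays open too, as does a difference between disease and health. Of the spike-in controls, which do not come from the cells, these 3 had 3' signals of 28.6 to 32.1 for Lys, 15.3 to 16.9 for Dap and 23.7 to 24.2 for Phe, against 16.1 to 20, 11.9 to 14.9 and 24.3 to 34.1 in the 18 libraries of neither set, all below the array medians.

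Other labellings of the samples did not reach either count: only the real split of 56 gave 1928 genes (highest other 1), and only the real split of 56 gave 748 (highest other 3). The libraries of low upper quartile all lie in the real patient groups. These splits therefore cannot tell a difference by disease from the placement of those libraries. Between CTCL and GVHD before ECP 0 genes passed in limma (175 at an unadjusted p under 0.05), a count that any split reaches (10 of 10), so the splits say nothing of it, and the highest other split gave 1766 genes. That split parts the 3 libraries of low upper quartile from the other 3, a structure of the samples that the disease labels do not follow. For the difference in change between CTCL and GVHD (0 genes in limma, 116 at an unadjusted p under 0.05), any split likewise reaches the count (100 of 100), and the highest, 1051, parts the same 3 libraries. With 10 splits of 3 against 3 samples a share under 0.05 is out of reach, which also holds within CTCL (3224, 1 of 10 splits, highest other 0) and GVHD (2906, 1 of 10 splits, highest other 3).

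For the all-donor count of 6458 genes only 1 of 100 splits, the real one, was as large (highest other 1560). For the 4081 genes of normal donors it was likewise 1 of 100 (highest other 1661). Both shares were under 0.05, which argues against chance, and 1 of 100 is the smallest share these splits can give. For the 21 lists called by camera over all donors, 5 of 100 splits gave as many and the highest other gave 23, so chance was not excluded.

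In 2 normal donor libraries, 1 before and 1 after ECP, the 3' end of control transcripts outshone the 5' end. The gap of the extreme library to the next, as a share of the group's range, was 0.918 before and 0.82 after ECP for the actin log2 ratio and 0.911 and 0.886 for the GAPDH ratio. The poly-A spike-in controls, bacterial transcripts added to the RNA and outside every comparison, had 3' signals of 926.1 and 535.7 for Dap, 209.7 and 145.4 for Lys, 191.8 and 123.3 for Phe and 256.4 and 168.2 for Thr in these libraries, against at most 16.9, 32.1, 34.1 and 33.1 in the other 21; the shares of range were 0.999 and 0.998 for Dap, 0.986 and 0.978 for Lys and 0.973 and 0.901 for Phe.

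RNA degraded before labelling was argued against as the whole cause of this bias, since the spikes, which never passed through the cells, were biased too (median log2 3'/5' ratio of at least 3.96 in the higher of the 2, a bound because their 5' signals, 11.8 to 20.1, were below the array medians). In the other 21 libraries the 3' signals of the spikes were also below the array medians. No library without actin bias therefore shows what ratio the spikes would have there. A second cycle of amplification, which the labels' protocol allows for some samples, stays a candidate explanation, with a ratio of at least 3.36 in both libraries. No biological explanation was tested.

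Of 380 sets of a named gene in the normal donors before (n = 5) or after ECP (n = 6), 37 had 1 library set apart by a share of range above Dixon's critical value, where chance gives about 1 in 20, or 19. In 19 of the 37 it was a 3' biased library. In that library before ECP, BAG3 (0.824), CD40 (0.713), HLA-DMB (0.715), HLA-DRA (0.749), PKM (0.746), PSMB10 (0.779), RPL22 (0.824) and XBP1 (0.716) were low, and CD274 (0.788), KCNMA1 (0.777), LAMP3 (0.764), TXNRD1 (0.712) and UTRN (0.763) were high. In that after ECP, CD1C (0.677), CD209 (0.678), IRAK2 (0.696), ITGB5 (0.626) and KCNMA1 (0.769) were high and RPL22 (0.634) was low. In other libraries before ECP, COXFA4L3 (0.716), EMP1 (0.822), HBD (0.743), MMP9 (0.797) and TCF4 (0.765) were high and CXCL1 (0.774) and PRF1 (0.755) low. After ECP, HERC5 (0.882), RSAD2 (0.785), TFPI2 (0.808), LRRN3 (0.666), NLRC5 (0.627) and TMEM204 (0.705) were high in 1 library, and BNIP3 (0.681), SLC2A3 (0.665), FSCN1 (0.702), IDO1 (0.755) and MDM2 (0.753) low.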

How the results depend on the processing

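The alternatives with a 3' bias or low upper quartile set were chosen after the data were seen; the others were planned. The 2 reversed results were LAMP2, at -0.12 under median scaling and -0.21 with an offset of 1, where the brightest of its probe sets became another one. Over named genes and all these alternatives, 7891 values kept their direction and side of the threshold, 338 lost the threshold, 18 gained it and 2 reversed; for lists these were 1217, 33, 10 and 0. With an estimated correlation 2 lists passed, and 1 with either set left out, as dendritic cell maturation went to an adjusted p of 0.0837 without the low upper quartile libraries and 0.0863 without the 3' biased ones, with medians of 1.13 and 1.07 against 1.09. Dim signals near the offset limit what can be seen at low levels.

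With array weights 5913 genes changed in CTCL, 4737 in GVHD, 3814 differed in change between patients and normal donors, and 5572 (CTCL) and 1411 (GVHD) differed from normal donors before ECP. Median scaling gave 1218 for GVHD before ECP, only the groups compared gave 488 for it, and leaving out the lowest 50% of genes, fewer genes tested, gave 1181 for CTCL before ECP. The cause was not tested for the weights, the scaling or the groups. With at least 2-fold required, the counts were 1726 for all donors, 1785 for CTCL, 1758 for GVHD, 1693 for normal donors, 840 for patients against normal donors, and 579 (CTCL) and 286 (GVHD) before ECP. Normal donors from the treatment device alone, fewer samples, gave 849 for patients against normal donors and 1012 (CTCL) and 426 (GVHD) before ECP.

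With the 3' bias as a block, 2172 genes differed in change between patients and normal donors, and 2963 (CTCL) and 1171 (GVHD) before ECP; the actin covariate also gave 2172. With the low upper quartile as a block these were 627, 112 and 432, with 1726 changed in CTCL. Without the libraries of low upper quartile they were 389, 4 and 291, with 889 in CTCL, and without both sets 506, 3 and 398, with 1405 in CTCL. In both, 1 gene (GLDC) differed in change between CTCL and GVHD and 2 (GLDC, GPRC5D) before ECP; the 4 for CTCL were these with MYBL2 and SHCBP1, and the 3 lacked SHCBP1. They rest on 1 CTCL library and were seen first and then named. The fits hold fewer samples.

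Leaving out each sample in turn gave 5853 to 6827 genes for all donors, 2057 to 3585 in CTCL, 2088 to 2531 in GVHD, 3486 to 4427 in normal donors, 1006 to 1733 for patients against normal donors, 311 to 2862 for CTCL and 147 to 944 for GVHD before ECP, 0 for both comparisons of CTCL with GVHD in limma (116 and 175 genes at an unadjusted p under 0.05 with all samples), and 19 to 21 lists. Counts moved over 1.5 times in CTCL without its sample 2 before ECP (2057); for CTCL before ECP without CTCL sample 2 (518) or 3 (311) or normal sample 2 (1094) or 5 (1271); and for GVHD before ECP without GVHD sample 4 (147) or 6 (347) or normal sample 2 (407) or 5 (498).

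With the replicate number as a block, 6177 genes changed in all donors, 2919 in CTCL, 2669 in GVHD, 3848 in normal donors, 1017 differed between patients and normal donors, 0 between CTCL and GVHD in limma (116 unadjusted without the block), and 21 lists passed. The numbers were not found to pair the samples: over 11 pairs the correlation of deviations lay between -0.276 and 0.243, 3 pairs were above 0.1, and 0 of 22 samples correlated best with its own number. Libraries of both sets that stood apart enter these correlations, which therefore cannot exclude that the numbers mark the same donors. As a random block the correlation was -0.0752, and no count of lists was made. Comparisons before ECP cannot be fitted with the fixed block; the random block gave 1933 genes for CTCL, 740 for GVHD and 0 between them in limma (175 unadjusted without the block).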

Other observations

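All tests in this part were added after the data were seen. The permutation test of gene length restates a pattern already noticed, and the tests on overnight incubation and on the brighter genes whose level went down as the cell scores went up, and the comparison of patients with normal donors after ECP, were chosen after the result was seen.

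After ECP, the interferon-induced genes RSAD2, IFIT1, CMPK2 and IFIT3 were higher in patients (n = 6) than in normal donors (n = 6) by 5.02 ± 1.08, 4.71 ± 1.10, 4.43 ± 0.79 and 4.14 ± 0.99, where before ECP the gaps were 1.90, 1.29, 1.26 and 1.32. IL6, the chemokine gene CCL8 and SPINK1 were higher by 4.88 ± 0.69, 4.27 ± 1.02 and 4.22 ± 0.32. All genes named for this comparison were chosen after their values were seen. The proteoglycan gene VCAN, the chemokine scavenger gene ACKR3, PLXDC2 and GPR160 were lower in patients (-3.09 ± 0.22, -3.48 ± 0.37, -2.89 ± 0.30 and -3.45 ± 0.33). In the limma fit 2009 genes differed after ECP, 973 higher and 1036 lower in patients. The 3 libraries of low upper quartile, all from before ECP, enter it through the shared normalisation and spread, and enter the gaps before ECP directly.

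Long genes were lower after ECP, a pattern noticed in these data. Of 957 genes spanning 200 kb or more (of 14784 with a length, 99.9% of those tested), 494 fell and 53 rose (51.6% and 5.54%), among them DPYD, UTRN, DIAPH2 and PRKCB, whereas of 10095 genes under 50 kb, 1640 fell and 2497 rose. The median level of long minus short genes was -0.338 ± 0.13 (SD) in 11 samples before and -1.13 ± 0.183 in 12 after ECP, a difference of -0.79 (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations give), with -0.875 in patients and -0.712 in normal donors (exact permutation test, p = 0.00216 in each).

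The 3' biased libraries were argued against as the cause, since the difference was -0.781 without them. A smaller 3' shift was not tested as a cause. In patients the actin log2 ratio was -0.0839 to 0.0864 before ECP and 0.2412 to 0.4565 after it. In normal donors outside the biased set the ranges overlapped, 0.03439 to 0.3217 before and 0.0252 to 0.6147 after ECP. Weak signal was also argued against. Among the brighter genes, the upper of 3 equal parts by mean level, long genes fell further than short ones (-1.24, 168 long genes, against -0.361 over all). Fewer lymphocytes and platelets could account for part of the pattern over all genes, where long minus short went to -0.12 among genes whose level went down as the marker scores of those cells went up over the samples before ECP. For those brighter genes this was argued against, with -1.33 among 51 such long genes. That holds for lymphocytes and platelets only, as monocyte markers, which also fell over all donors, had no such test. The samples before ECP that set the scores include libraries of both sets that stood apart. A block to transcription by psoralen crosslinks, which would strike long genes more often, is one hypothesis that was not tested apart from overnight incubation. With 0 samples incubated overnight without ECP, the treatment and the incubation cannot be told apart.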
